A study of Drosophila melanogaster with 25 samples.

How the data were processed

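DNA copy number was measured by comparative genomic hybridisation on 25 Agilent tiling arrays of the Drosophila genome (build dm3, release 5, per the file headers). Each array holds 1 sample of 100 stage 13 egg chambers of 1 genotype, labelled with Cy5 (red), and Oregon R embryo DNA, labelled with Cy3 (green), per the labels. All arrays have the same dye orientation, so a positive log2 ratio means more DNA in the egg chambers. The samples were grouped by their titles into mus101, H2Av_dCT, chk1, chk2, ligIV, spnA and brca2 (3 arrays each) and chk2_CyO and DNL4 (2 arrays each). The genotype field of chk2 and chk2_CyO is the same, and only the titles tell them apart. chk2_CyO, the only group titled as a balancer heterozygote, served as the comparator. Wild-type egg chambers were not analysed here. The labels do not say whether arrays of a group come from separate cultures, so p-values measure only the spread between these samples, which may be technical.

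The red and green intensity values of each spot were deposited as scanner output. Per the file headers, Feature Extraction 10.1.1.1 subtracted the background and applied a linear dye normalisation within each array. The deposited BED tables hold log2 ratios that are smoother along the chromosome than the scanner values. The smoothing and normalisation behind these log2 values are not given in the sources used here. They served as an alternative.

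From the processed intensities, log2(red/green) was computed per probe, without control spots and outlier flags, and centred on each array's autosomal median. Probes were summarised as medians of 1 kb bins. At each of the 6 follicle-cell amplicons, the common peak was the highest bin of the mean of the 9 group means after a running mean over 5 bins. The local baseline was the median of the bins 150 to 300 kb from the peak. The height was the highest smoothed value within 5 kb of the peak, over the baseline. The half-maximum width was the distance between the first points on both sides at which the linear copy number above baseline fell to 50% of its peak value. It was read only where the height was at least 1.5-fold. DAFC-22B did not reach this height in any H2Av_dCT or spnA array, so mean widths cover the 5 sites read on every array, a choice made after the values were seen.

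Widths and heights were compared with limma 3.58.1 in R 4.3.3 (summaries in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3) over all 25 arrays, with array design (A on 1 array, B on 6, C on 18) as a covariate. Benjamini-Hochberg adjustment ran over the site-by-genotype tests, over the means, and over the 5 contrasts between mutants with their sites. A value was called at an adjusted p under 0.05. The design term gives no weight to mus101 replicate 1, the only array of design A. Contrasts that missing values or design left with fewer arrays were fitted by least squares on the measured arrays. Exact two-sided permutation tests (scipy 1.17.1) stand beside the means. The exact permutation p cannot go below 0.2 for 3 arrays against 2, 0.333 for 2 against 2, or 0.1 for 3 against 3. The 1 kb bins within 100 kb of the peaks, and 14282 bins outside them that every array measured, were tested with the same design and a variance trend. The interaction of site and genotype was an F test on the difference of log2 width between each pair of sites. The tests and alternatives were fixed before the data were examined, except those named as chosen later.

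The sites named are all 6 amplicons, the further regions at 1.5-fold or more over at least 5 consecutive bins, and, outside the sites, at most 5 runs of 5 or more called bins per contrast. Stretches in which 1 genotype stands apart (a running median over 11 bins more than 0.6 from the median of the groups, over at least 5 bins) were sought by a rule chosen after the data were seen. No gene positions on dm3 were used here, so the copy number of the targeted genes themselves is not reported. Only background names of genes are given.

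The alternatives were a fit without array design, design C arrays alone, the replicate number as a block, normexp background correction (offset 50), the BED values, other smoothing, baseline, peak position and width measures, a probe filter, another comparator, a set test, leaving out each array, and scan session as a block. Further alternatives were added after the data were seen. They left out the noisiest or doubted arrays, took the scan as a fixed block, or as a random block for the bins, used the share of red probes above background as a covariate, averaged heights without DAFC-22B, or tested all bins of 24 arrays. The scripts were tested on simulated data. For ligIV against chk2_CyO, 92% of bins near the peaks changed by 1 log2 unit and 52% of those changed by 0.5 were recovered among 1114 bins, with 8 unchanged bins called. Among the 14282 bins outside, 90% and 31% were recovered, with 5 unchanged bins called. A difference of -0.5 in mean log2 width was called in 55% of 300 simulations. The noise of these simulations was independent between bins or sites and between arrays, without scan sessions. Their shares of recovered and false calls therefore do not cover effects that the arrays of a session share. In simulated peaks, widths read between 79.4% and 105% of the true width at the median noise of the arrays, and between 28.9% and 78.7% at that of the noisiest array.

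Red signal was well above background for 50.1% to 99.8% of the probes, depending on the array. The lowest share belongs to chk2 replicate 1. The number of arrays limits the precision of every comparison.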

Results

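In the follicle cells of the Drosophila ovary, a few short regions of the genome are amplified by repeated firing of origins. By stage 13 the replication forks have moved outward from these origins, so copy number falls off with distance from a central peak. The series asks how far forks progress when genes of the DNA damage checkpoint or of double-strand break repair are mutated. Copy number was measured in 25 samples of 100 stage 13 egg chambers against DNA of 0 to 2 h embryos. The 9 groups were mus101, H2Av_dCT, chk1, chk2, ligIV, spnA and brca2 with 3 arrays each, and DNL4 and chk2_CyO with 2 arrays each. Mus101 is the fly TopBP1, chk1 and chk2 are checkpoint kinases, and H2Av_dCT carries the histone variant H2Av without its C-terminal tail. The ligIV and DNL4 groups carry alleles named for DNA ligase IV of end joining, and brca2 acts in homologous recombination. Each mutant was set against chk2_CyO, the group titled as a balancer heterozygote. The arrays held 173496 to 175932 probes, and their red signal was well above background for 50.1% to 99.8% of them.

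The 6 known amplicons were found in the mean of all groups. DAFC-66D, the chorion gene cluster on chromosome 3L, was the highest, with a log2 ratio of 5.20 over the autosomes in the bin 8719001 to 8720000. DAFC-7F, the chorion gene cluster on X, measured 3.34 in the bin 8380001 to 8381000. The peaks of DAFC-34B (2L, 13405001 to 13406000), DAFC-30B (2L, 9531001 to 9532000), DAFC-62D (3L, 2273001 to 2274000) and DAFC-22B (2L, 1901001 to 1902000) reached 2.06, 1.5, 1.5 and 1.26. In chk2_CyO the fold over the local baseline was 39.6 ± 1.33 at DAFC-66D (SD, n = 2) and 11.3 ± 0.443 at DAFC-7F. It was 5.77 ± 0.517 at DAFC-34B, 3.45 ± 0.126 at DAFC-22B, 3.21 ± 0.0943 at DAFC-30B and 2.91 ± 0.148 at DAFC-62D. A search of the genome for bins at 1.5-fold or more found 12 regions, of which 3 lay outside these sites. Of these 3, those on X had mean log2 ratios of 0.75 and 0.77 over the autosomes, where the median of all of X was 0.37. At 2-fold 0 regions lay outside the sites, and with normexp background correction 11 did.

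**Figure D1:**
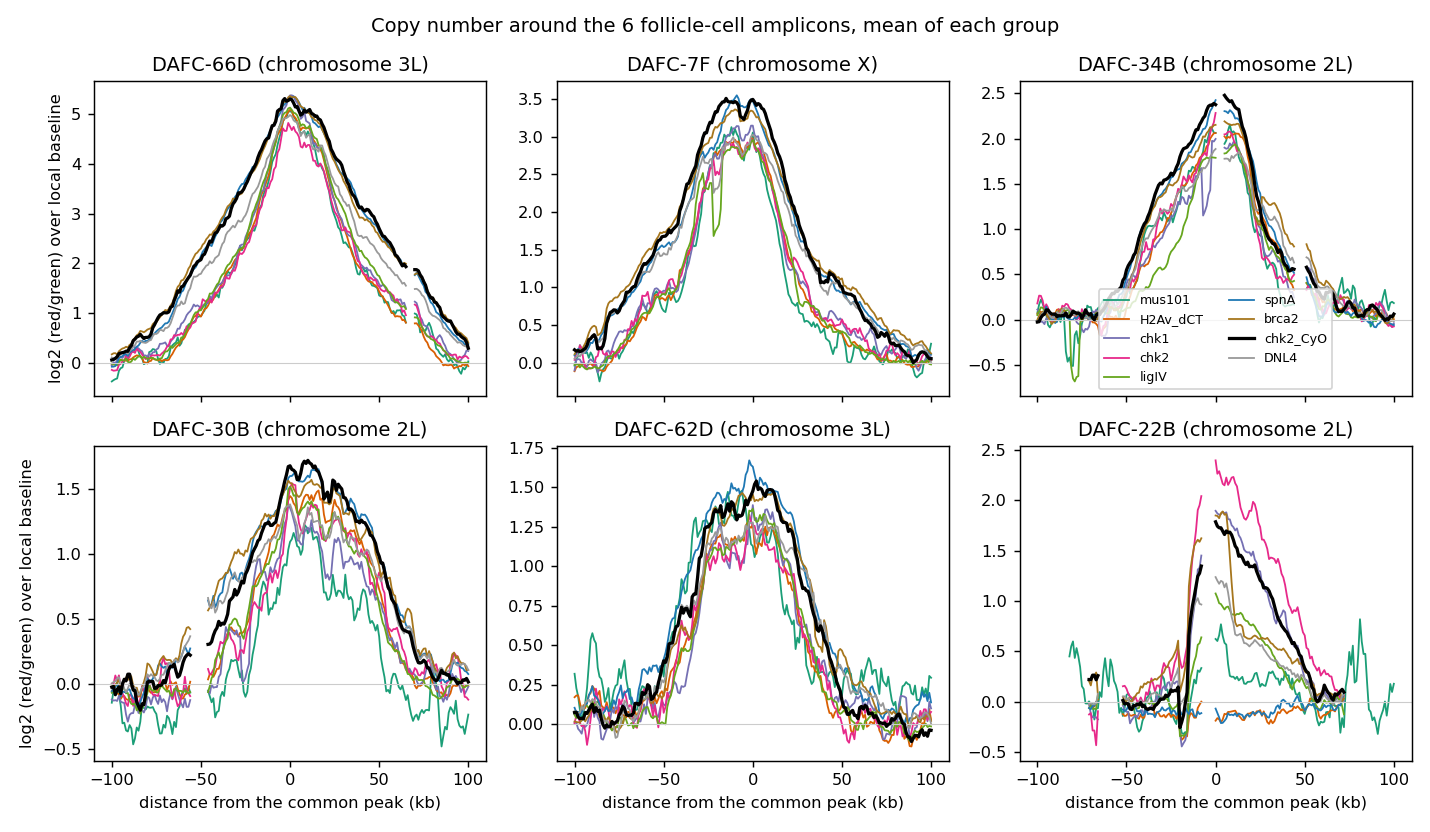
Log2 copy number over the local baseline against distance from the common peak in kb, as the smoothed mean of each group at each of the 6 amplicons (n = 3 arrays per group, 2 for chk2_CyO and DNL4). At 20 to 40 kb from the peaks of 5 sites the mus101, H2Av_dCT, chk1, chk2 and ligIV means lie between 1.14 and 1.29, and those of chk2_CyO, spnA and brca2 between 1.81 and 1.83.

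The flanks of the amplicons carried less DNA in 5 mutants than in chk2_CyO. At 20 to 40 kb from the peaks, the mean log2 ratio over the 5 sites was 1.81 ± 0.01 in chk2_CyO (SD, n = 2). It was 1.14 ± 0.10 in mus101, 1.24 ± 0.09 in chk1, 1.26 ± 0.10 in ligIV, 1.26 ± 0.33 in chk2 and 1.29 ± 0.08 in H2Av_dCT (n = 3 each). It was 1.83 ± 0.26 in spnA and 1.81 ± 0.16 in brca2 (n = 3 each), and 1.60 ± 0.10 in DNL4 (n = 2). All 15 arrays of the 5 mutants with lower means lay at or below 1.53, under both chk2_CyO arrays. Both DNL4 arrays (1.54 and 1.67), brca2 replicate 3 (1.65) and spnA replicate 1 (1.53) lay under them too. The difference was smaller at the centre, where mus101 differed from chk2_CyO by -0.40 within 5 kb of the peak and by -0.67 at 20 to 40 kb. For ligIV these differences were -0.35 and -0.55, and for H2Av_dCT -0.34 and -0.52.

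**Figure D2:**
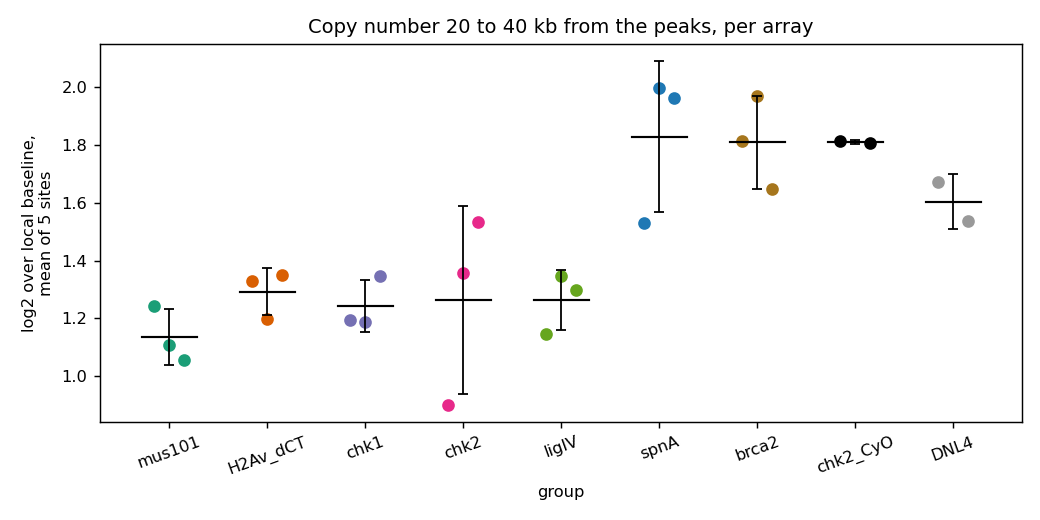
Log2 copy number over the local baseline, averaged over 20 to 40 kb from the peaks of 5 amplicons, for each array (points) by group, with the group mean and SD (bars; n = 3, or 2 for chk2_CyO and DNL4). The chk2_CyO mean is 1.81 and the mus101 mean is 1.14.

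Of the 1114 bins tested within 100 kb of the peaks, limma called 361 lower and 2 higher in mus101 than in chk2_CyO. It called 326 lower in ligIV, 307 lower in H2Av_dCT and 109 lower in chk1, with none higher in these 3. In chk2, 269 bins were lower and 45 higher, and 36 of the higher bins lay at DAFC-22B. In spnA 50 bins were lower, all at DAFC-22B, and 1 was higher. Only 7 bins were called in brca2 and 2 in DNL4, all lower. At DAFC-66D between 72 and 141 bins were lower in each of the 5 mutants, and at DAFC-7F between 23 and 114. Fewer were lower at the other sites, with 8 to 30 per mutant at DAFC-30B, 1 to 48 at DAFC-34B, 1 to 30 at DAFC-62D and 0 to 56 at DAFC-22B. As a share of the bins at each distance, lower calls over all 6 sites were highest at 20 to 40 kb in each of the 5 mutants. In mus101 the share was 44.2% at 10 to 20 kb, 49.0% at 20 to 40 kb and 30.8% at 40 to 80 kb, and in ligIV it was 24.2%, 38.1% and 33.6%. All 8 contrasts share the 2 chk2_CyO arrays, and the total of 1479 called bins fell to 441 without the first of them and 584 without the second. Without the first or second of them the counts were 155 and 173 in mus101, 160 and 190 in H2Av_dCT, 2 and 3 in chk1, 1 and 44 in chk2, and 81 and 134 in ligIV. The mus101 count fell to 29 without mus101 replicate 3, and the chk2 count to 164 without chk2 replicate 1. The chk1 count lay between 2 and 229 as each array was left out. It was 4, 42 and 2 without chk1 replicates 1, 2 and 3, it was 229 and 174 without chk2 replicates 1 and 3, and it was 212 without spnA replicate 1. It was 45, 65 and 62 without H2Av_dCT replicates 1, 2 and 3, 56 without chk2 replicate 2, 51 without mus101 replicate 2 or 3, 68 without brca2 replicate 1 and 70 without ligIV replicate 3. With at least 2 probes per bin it was 5, and with the deposited log2 values or design C arrays alone 2. With normexp background correction the counts were 23 in mus101, 171 in H2Av_dCT, 3 in chk1, 218 in chk2, 79 in ligIV and 38 in spnA, and 0 in brca2 and DNL4, where 58 and 50 bins had an unadjusted p under 0.05. As each array was left out, the counts of brca2 and DNL4 stayed between 0 and 26. The fit with array design gives no weight to mus101 replicate 1, the only array of its design.

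The arrays were scanned in 13 sessions, and none of the sessions of mus101, H2Av_dCT, chk1, chk2 and ligIV held a chk2_CyO array. The only session they shared with another group was that of spnA replicate 1, scanned with arrays of H2Av_dCT and chk1. It links them to spnA and not to chk2_CyO, with which no spnA array was scanned. In that session the 20 to 40 kb value was 1.53 in spnA, 1.33 in H2Av_dCT and 1.2 in chk1, with 1 array each. Against spnA, the mean difference 10 to 40 kb from the peaks was -0.70 in mus101 and -0.33 with the scan session as a block. It moved from -0.54 to -0.24 in ligIV, from -0.52 to -0.25 in chk1, from -0.48 to -0.17 in H2Av_dCT and from -0.55 to -0.09 in chk2. With that block, bins called lower than in spnA numbered 210 in mus101, 214 in H2Av_dCT, 155 in chk1, 179 in ligIV and 52 in chk2. Bins called higher numbered 33, 16, 74, 41 and 64, so in chk2 more were higher than lower. Unlike the mean differences, these counts include DAFC-22B, which was not amplified in spnA. They were not split by site, so they do not show whether the higher bins lie in the flanks of the other sites.

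Half-maximum width summarises the spread of each amplicon. The mean over 5 sites was 49.1 ± 0.0447 kb in chk2_CyO (SD, n = 2), 51.2 ± 0.727 kb in DNL4 (n = 2), 50.9 ± 2.26 kb in brca2 and 48.0 ± 3.82 kb in spnA (n = 3 each). It was 44.0 ± 2.26 kb in H2Av_dCT, 36.1 ± 2.98 kb in ligIV, 33.5 ± 9.64 kb in chk2, 33.2 ± 9.14 kb in chk1 and 29.2 ± 12.4 kb in mus101 (n = 3 each). The mus101 arrays read 15.1, 34.3 and 38.2 kb, the lowest in replicate 1, whose noise between neighbouring bins was 0.63. At DAFC-62D the lowest mus101 width was 2.0 kb. No mean width passed limma's adjusted threshold against chk2_CyO. The fitted log2 difference was -0.53 in chk2, -0.47 in chk1 and -0.45 in ligIV, each at an adjusted p of 0.161. The chk2 difference was -0.21 without chk2 replicate 1, the noisiest array, and -0.71 without replicate 3, and the chk1 difference was -0.73 without chk1 replicate 3. It was -0.34 in mus101 (adjusted p = 0.367), -0.09 in H2Av_dCT, 0.03 in spnA, 0.05 in brca2 and 0.06 in DNL4 (adjusted p = 0.892 each). All 3 arrays of mus101, H2Av_dCT, chk1, chk2 and ligIV were narrower than both chk2_CyO arrays, with an exact permutation p of 0.2, the smallest that 3 arrays against 2 allow. Of the 46 single-site widths, limma called 0, and 6 had an unadjusted p under 0.05. The count rose to 4 and 2 without DNL4 replicates 1 and 2, to 2 without chk2 replicate 1 and to 1 without ligIV replicate 3. A set test over sites (fry) passed no genotype either, with a lowest adjusted p of 0.0947.

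Those 6 widths were chk1 and chk2 at DAFC-66D (log2 differences -0.69 and -0.58), chk2 and ligIV at DAFC-30B (-0.74 and -0.89), ligIV at DAFC-7F (-0.64) and brca2 at DAFC-22B (-0.74). Their adjusted p lay between 0.0867 and 0.153. The noise between neighbouring bins averaged 0.47 in chk2 and 0.44 in mus101, and between 0.20 and 0.31 in the other groups. Within chk1 it was 0.38 and 0.39 in replicates 1 and 2, whose mean widths were 30.3 and 25.9 kb. In chk1 replicate 3 it was 0.17, with a mean width of 43.5 kb, so the chk1 width difference is limited by noise too. H2Av_dCT replicate 1, at a noise of 0.37, read 41.4 kb. Simulated widths read 28.9% to 78.7% of their true length at the noise of the noisiest array, which was chk2 replicate 1. With normexp background correction or the deposited log2 values, the mean widths of mus101, chk1 and ligIV passed the threshold, and with the deposited values that of chk2 too. With smoothing over 11 bins mus101, chk1 and chk2 passed, and with area over height chk2 and ligIV. Single-site widths called in these last fits numbered 11 and 13.

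**Figure D3:**
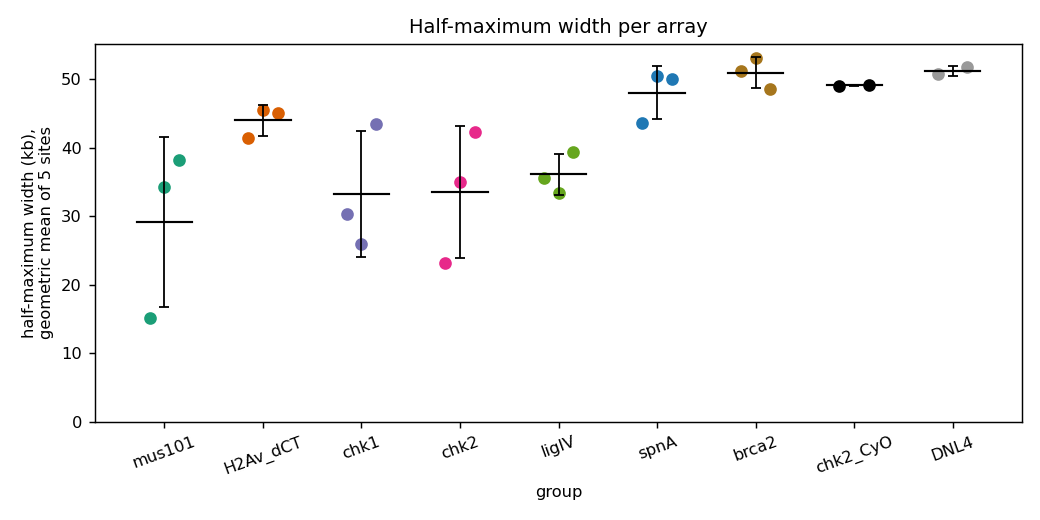
Half-maximum width in kb, as the geometric mean over 5 amplicons, for each array (points) by group, with the group mean and SD (bars; n = 3, or 2 for chk2_CyO and DNL4). The ligIV arrays lie between 33.4 and 39.3 kb and the chk2_CyO arrays between 49.0 and 49.1 kb.

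Peak height measures how far the origins themselves were amplified. Averaged over the 6 sites, log2 height was lower than in chk2_CyO by limma in mus101 (-0.61) and H2Av_dCT (-0.59), each at an adjusted p of 0.0235. Within a scan session heights had an estimated correlation of 0.87, and no mus101 or H2Av_dCT array shared a session with chk2_CyO. These height differences therefore cannot be told apart from the scan. The differences in DNL4 (-0.42), ligIV (-0.39), spnA (-0.30), chk1 (-0.21), chk2 (-0.13) and brca2 (-0.08) did not pass. Without DAFC-22B, the means of mus101 (-0.50, adjusted p = 0.162) and H2Av_dCT (-0.33, adjusted p = 0.164) did not pass either, and that of spnA was 0.0084. Over 6 sites both calls also ended without array design, with normexp, with the deposited log2 values, with the probe filter and against the mean of the other groups, where the adjusted p lay between 0.0591 and 0.673. With design C arrays alone the mus101 call ended (adjusted p = 0.0644). With scan as a random block, the mean heights of spnA (-0.60), ligIV (-0.50), DNL4 (-0.42) and brca2 (-0.24) passed as well. Of the 48 single-site heights, limma called 9, all lower. They were mus101 at DAFC-7F (-0.64), DAFC-62D (-0.52) and DAFC-22B (-1.14), H2Av_dCT at DAFC-7F (-0.53) and DAFC-22B (-1.87), ligIV at DAFC-7F (-0.53) and DAFC-34B (-0.65), spnA at DAFC-22B (-1.82) and DNL4 at DAFC-34B (-0.64). The count fell to 3 or 2 without chk2_CyO replicate 1 or 2 and to 4 without mus101 replicate 2 or 3, and rose to 14 without chk2 replicate 1. The means of mus101 and H2Av_dCT lost their call without chk2_CyO replicate 1 (adjusted p = 0.0698) or 2 (adjusted p = 0.129). That of mus101 also lost it without mus101 replicate 3 (-0.53, adjusted p = 0.131) and that of H2Av_dCT without H2Av_dCT replicate 2 (-0.49, adjusted p = 0.08). At DAFC-7F the H2Av_dCT call also ended without H2Av_dCT replicate 2 or 3 (-0.44 and -0.57), and the ligIV call without ligIV replicate 1 or 2 (-0.44 and -0.54).

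DAFC-22B was the site at which log2 height differed most between genotypes. It was 0.927 ± 0.035 fold over the local baseline in H2Av_dCT and 0.956 ± 0.0922 in spnA (SD, n = 3 each), so no array of either group showed amplification there. It was 3.45 ± 0.126 fold in chk2_CyO (n = 2), 3.76 ± 0.246 in chk1, 3.89 ± 1.28 in brca2, 5.44 ± 1.64 in chk2, and 2.11 ± 0.202 in ligIV (n = 3 each). In mus101 it was 1.88 ± 0.626 (n = 3) and in DNL4 it was 1.63 in replicate 1 and 3.5 in the library labelled replicate 2. The adjusted p of limma's test was 6.56e-05 for both H2Av_dCT and spnA. Both calls held in all 20 fits that gave a value, which include the removal of each array of the contrast. The other 5 sites were amplified in all 6 arrays of both groups.

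Mutants were then compared with each other, to set end joining against homologous recombination, the checkpoint kinases against each other, and alleles of the same pathway side by side. Of the 2 DNL4 arrays, the library labelled replicate 2 carried copy number gains seen otherwise in the brca2 arrays, so its label is in doubt. Mean widths in ligIV were lower than in brca2 by -0.50 (log2, adjusted p = 0.0986), than in spnA by -0.48 (adjusted p = 0.109) and than in DNL4 by -0.51 (adjusted p = 0.109), which did not pass limma's threshold. The set test over sites (fry) passed each of them, at an adjusted p of 0.0355, as did limma with normexp or the deposited log2 values. All 3 ligIV arrays were narrower than every spnA and brca2 array, with an exact permutation p of 0.1, the smallest for 3 against 3. No ligIV array shared a scan session with an spnA, brca2 or DNL4 array, so these comparisons do not separate genotype from scan. At DAFC-30B the ligIV width was called lower than in spnA (-1.18, adjusted p = 0.00565), brca2 (-1.08, adjusted p = 0.00578) and DNL4 (-0.92, adjusted p = 0.0321). At DAFC-7F it was called lower than in brca2 (-0.66, adjusted p = 0.0268) and not than in spnA (-0.49) or DNL4 (-0.50), both at an adjusted p of 0.109. Without ligIV replicate 2 the DAFC-30B differences from spnA and brca2 were -0.88 and -0.78, each at an adjusted p of 0.0891. The difference from DNL4 at DAFC-30B lost its call without ligIV replicate 1 (-0.88) or 2 (-0.63) or either DNL4 array (-0.87 and -0.98). That from brca2 at DAFC-7F lost it without any ligIV array (-0.69, -0.66 and -0.64) or brca2 replicate 1 or 2 (-0.65 and -0.63). Without DNL4 replicate 1, which leaves only the library labelled replicate 2, the DAFC-7F difference from DNL4 was -0.85. At DAFC-22B the ligIV width was higher than in brca2 by 0.60, with an adjusted p of 0.081. The mean widths of chk1 and chk2 differed by 0.06 (adjusted p = 0.862) and those of spnA and brca2 by -0.02 (adjusted p = 0.941).

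Whether genotypes shortened some amplicons more than others was tested on pairs of sites. None of the 10 pairs of sites differed in its width differences between genotypes by limma's F test, and 0 had an unadjusted p under 0.05. A permutation of the genotype labels gave p = 0.197. Without chk2 replicate 1, 3 pairs were called. With smoothing over 11 bins 7 pairs were called, and with area over height as the width 2.

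Outside the amplicons, copy number differed at few of the 14282 bins. Each bin was tested in each of the 8 contrasts. Summed over these contrasts, limma called 294 tests, 146 lower and 148 higher, and 7105 tests had an unadjusted p under 0.05. In chk1 a run on 2R, 981001 to 988000, was higher than in chk2_CyO by 2.02 log2 units. In spnA a run on 2R, 3128001 to 3138000, was higher by 1.1. In ligIV adjacent runs on 2L, 17936001 to 17956000 and 17957001 to 17968000, were higher by 0.96 and 0.93, and a run on 3R, 6989001 to 6995000, by 0.83. In H2Av_dCT a run on 3R, 6821001 to 6830000, was higher by 0.90. The total was 123 or 155 without chk2_CyO replicate 1 or 2, 494 without chk2 replicate 1 and 1452 without chk2 replicate 3.

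Larger stretches, sought by a rule chosen after the data were seen, bear on the genotype labels. The spnA label names a deficiency, Df(3R)X3F, and the spnA arrays had a lower stretch on 3R, 25756001 to 25902000, at -0.84 ± 0.01 (SD, n = 3). No other array that measured it was below -0.06. A stretch on 2L, 10873001 to 10898000, was at -0.56, -1.63 and -3.66 in the chk2 arrays and at -0.84 and -1.09 in those of chk2_CyO. The brca2 arrays had gains on 3L at 7469001 to 7514000 (0.88 ± 0.06) and 11688001 to 11698000 (0.92 ± 0.02, SD, n = 3). The library labelled DNL4 replicate 2 carried both gains, at 0.72 and 0.71, and DNL4 replicate 1 did not, at 0.05 and -0.03. Without that library and brca2 replicate 3, 9 bins near the peaks were called in DNL4 and 19 in brca2. The median log2 ratio of chromosome X was 0.37 ± 0.08 over the 25 arrays (SD).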

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

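The tests of the flanks, of DAFC-22B and of the library labelled DNL4 replicate 2 were chosen after the result was seen, and the splits of the arrays were planned.

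In some genotypes every array moved up at 1 site and every array moved down at another site, relative to chk2_CyO. These differences between sites were not tested themselves, and they are differences of group means without the design term. The 8 contrasts against chk2_CyO were screened for log2 height and log2 width, and only those that met this rule are listed. With so few arrays per group, some contrasts can meet it by chance, and how many would was not worked out. The list therefore does not show that a genotype acts differently on different sites. In chk2 the log2 height was higher at DAFC-22B (0.61) and lower at DAFC-34B (-0.24) and DAFC-7F (-0.44). In spnA the log2 width was higher at DAFC-30B (0.10) and DAFC-62D (0.081) and lower at DAFC-66D (-0.066) and DAFC-7F (-0.20). In brca2 it was higher at DAFC-30B (0.19) and DAFC-34B (0.13) and lower at DAFC-22B (-0.74) and DAFC-66D (-0.13). In DNL4, which has 2 arrays, it was higher at DAFC-34B (0.32) and DAFC-62D (0.25) and lower at DAFC-66D (-0.15). The comparator has 2 arrays as well.

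The flanks of the amplicons were lower in mus101, H2Av_dCT, chk1, chk2 and ligIV than in chk2_CyO. A dim red channel as the whole cause is argued against in H2Av_dCT and ligIV, which had at least 337 bins called lower with the share of red probes above background in the fit and at least 79 with normexp. In mus101 and chk1 the counts of these fits do not decide, with at least 186 bins in the first but 23 and 3 with normexp. The size of the difference did not shrink with normexp: at 20 to 40 kb it went from -0.67 to -0.89 in mus101 (SD between arrays 0.10 before and 0.06 after) and from -0.57 to -0.76 in chk1 (0.09 and 0.26). The SD between the chk2_CyO arrays rose from 0.0058 to 0.10, and what ended the calls was not tested. Without the probes near background at least 98 bins were lower in both, so these probes alone do not account for all the calls. Red signal was well above background for 89.7% to 97.4% of probes in mus101 and 94.0% to 99.4% in chk1. The filter therefore removes few red probes, and it does not decide about a dim channel. It was added last, with its counts already known. In chk2 a dim channel stays open, with 11 bins in the fit with that share but 119 without chk2 replicate 1, the dimmest array. The scan session cannot be told apart from genotype. With the scan as a block at least 52 bins per genotype were called lower than in spnA, but in chk2 64 were called higher. These counts include DAFC-22B, which was not amplified in spnA, and were not split by site. A single spnA array links these genotypes to spnA by session, and no array links them to chk2_CyO. The biological difference that the design names, the genotype, may also explain the lower flanks and was not tested apart from the scan.

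DAFC-22B was not amplified in H2Av_dCT and spnA. Noise of dim arrays is argued against, since the other 5 sites differed from chk2_CyO in mean log2 height by -0.31 in H2Av_dCT and 0.027 in spnA, and DAFC-22B by -1.90 and -1.86. A strain variant shared by both stocks stays open. The H2Av_dCT arrays averaged -0.023 at the 6 probes near the site that are lowered in spnA, which alone would argue against a shared haplotype, but 6 probes are few and brca2 itself averaged -0.57 there. The genotypes may act on this site, or the stocks may carry different variants of it, and the design has no sister stock to separate these.

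The library labelled DNL4 replicate 2 carried gains on 3L seen otherwise in the brca2 arrays. At the first gain it measured 0.72, and no other array outside brca2 was above 0.19, which argues against noise. DNL4 replicate 1 measured 0.050 there, so it did not carry this stretch of 3L. That is 1 array at 1 stretch, and it does not decide whether the stocks share other chromosomes. At 47 probes lowered in both DNL4 arrays, the brca2 arrays measured -3.62, -3.08 and -3.04. At probes lowered in brca2, the median of DNL4 replicate 1 was not below -0.19. The ratio of the gain to the 2L stretch raised in every genotype was 0.971 in this library and 0.975 ± 0.0800 in brca2 (SD, n = 3), as a wrong label would give. A mixed sample stays open, since the library measured -1.16 at probes lowered in brca2, where the brca2 arrays were at or below -2.45, but other dim arrays were also weak at the probes of their own group, such as chk2 replicate 1 at -0.89.

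For pairs of mutants with 3 arrays each, the 6 arrays make 10 splits, too few for a share under 0.05. In each pair 1 split, the real one, gave the highest count of bins near the peaks. The real counts were 2 for chk1 against chk2, 59 for spnA against brca2, 373 for ligIV against spnA and 479 for ligIV against brca2, and the highest of the other splits gave 0, 0, 0 and 1. Of the 59 bins of spnA against brca2, 54 lay at DAFC-22B. The ligIV, spnA and brca2 groups shared no scan session with each other, so the counts between them do not separate genotype from scan.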

How the results depend on the processing

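The fits without mus101 replicate 1 and chk2 replicate 1, without the doubted DNL4 and brca2 arrays, with scan as a fixed block, of the bins with scan as a random block, with the share of red probes as a covariate, with mean height without DAFC-22B and with all bins of 24 arrays were chosen after the data were seen. The planned fit, which called 0 widths against chk2_CyO, stays the reported result, and the fits that call more are alternatives to it. Where a value below changed, the cause was not tested.

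In the fit without array design, the log2 heights of mus101 (-0.41) and H2Av_dCT (-0.58) lost their call, 4 heights and 154 bins outside the peaks were called, and the width differences of spnA from chk2_CyO (-0.034) and of chk1 from chk2 (-0.0020) reversed. With design C arrays alone, the mus101 height (-0.67) lost its call, and 4 heights and 163 outside bins were called. With the replicate number as a block, the mean widths of spnA (-0.093) and brca2 (-0.019) reversed and 4 widths were called. The numbers do not pair the arrays: 93 pairs of the same number had a median correlation of 0.08.

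With normexp correction the mean widths of mus101 (-0.44), chk1 (-0.41) and ligIV (-0.45) passed, as did ligIV against DNL4 (-0.51), spnA (-0.52) and brca2 (-0.50), and 4 widths were called. The differences of chk1 from chk2 (-0.097) and of spnA from brca2 (0.015) reversed. The heights of mus101 (-0.47) and H2Av_dCT (-0.59) lost their call, and 2 heights, 532 bins near the peaks, 149 outside and 21 amplified regions were called. The spnA stretch on 3R moved to -0.64. With the deposited log2 values the mean widths of mus101 (-0.35), chk1 (-0.37), chk2 (-0.37) and ligIV (-0.33) passed, as did ligIV against DNL4 (-0.46), spnA (-0.36) and brca2 (-0.35). The difference of spnA from brca2 reversed (0.0069), the heights of mus101 (-0.54) and H2Av_dCT (-0.46) lost their call, 6 widths and 2 heights were called, and the spnA stretch moved to -0.61.

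Without smoothing, the mean width of DNL4 (-0.38), chk1 at DAFC-66D (0.11), ligIV against brca2 at DAFC-22B (-0.016) and the mean height of chk2 (0.033) reversed. With smoothing over 11 bins, the mean widths of mus101 (-0.32), chk1 (-0.27) and chk2 (-0.30) passed, as did ligIV against DNL4 (-0.38), spnA (-0.25) and brca2 (-0.29), with 11 widths and 7 pairs of sites called. With the width read at 50% of the log2 height, 7 widths were called. With area over height as the width, chk2 (-0.35), ligIV (-0.31) and ligIV against DNL4 (-0.44), spnA (-0.34) and brca2 (-0.44) passed, 13 widths and 2 pairs of sites were called, and ligIV against brca2 at DAFC-22B reversed (-0.0035). The set test gave an adjusted p of 0.0355 for ligIV against each of DNL4, spnA and brca2. With the probe filter the heights of mus101 (-0.61) and H2Av_dCT (-0.59) lost their call, 3 heights, 3 widths and 189 outside bins were called, and ligIV against spnA at DAFC-7F reversed (0.032). With 5 kb bins 391 bins near the peaks and 100 outside were called, of fewer tested. Centring on all probes moved chromosome X to 0.29.

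Against the mean of the other groups, the heights of mus101 (-0.35) and H2Av_dCT (-0.32) lost their call, those of brca2 (0.25), chk2 (0.19), chk1 (0.11) and spnA (0.0054) reversed, as did the width of H2Av_dCT (0.11), and 1661 outside bins were called. With scan as a random block, the heights of spnA (-0.60), ligIV (-0.50), DNL4 (-0.42) and brca2 (-0.24) passed, 16 heights were called, and the widths of spnA (-0.014) and of chk1 from chk2 (-0.056) reversed. Scan as a fixed block cannot estimate the 5 genotypes with lower flanks or spnA against chk2_CyO. It leaves DNL4 and brca2 each with 1 array scanned beside 1 chk2_CyO array, and for brca2 that is replicate 3, a doubted array. In these the log2 height differed by -0.38 in DNL4 and -0.31 in brca2, and the brca2 width reversed (-0.015). The width difference of chk1 from chk2 reversed too (-0.35).

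Without mus101 replicate 1 and chk2 replicate 1, the mean widths of chk1 (-0.41) and ligIV (-0.45) passed, as did ligIV against DNL4 (-0.51), spnA (-0.51) and brca2 (-0.50), and the heights of ligIV (-0.39) and DNL4 (-0.42). The height of chk2 (0.073) and the widths of chk1 from chk2 (-0.20) and spnA from brca2 (0.0081) reversed, and 2 widths, 14 heights, 3 pairs of sites and 494 outside bins were called. Without the doubted DNL4 and brca2 arrays the brca2 height reversed (0.016). With all bins of 24 arrays 1575 outside bins were called, of more tested.

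With the mean height without DAFC-22B, mus101 (-0.50) and H2Av_dCT (-0.33) lost their call and spnA reversed (0.0084).

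Leaving out each array, the mean log2 heights ranged from -0.67 to -0.53 in mus101, from -0.65 to -0.49 in H2Av_dCT, from -0.29 to 0.073 in chk2 and from -0.16 to 0.016 in brca2. Width differences ranged from -0.20 to 0.24 for chk1 from chk2 and from -0.056 to 0.0079 for spnA from brca2. Counts ranged from 0 to 4 widths, 2 to 14 heights, 0 to 3 pairs of sites, 441 to 1841 bins near the peaks and 123 to 1452 outside. With 1 chk2_CyO or DNL4 array left, that array is assumed to vary like the other groups.

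Over the same alternatives, the called lower heights of DAFC-22B in H2Av_dCT (-2.40 to -1.46) and spnA (-2.38 to -1.38) stayed called in 20 of 20 fits. The next counts take each value under each alternative as 1 case. Flank differences moved by less than the spread between arrays in 289 cases and by more in 26. Single-site heights kept direction and side of the threshold in 218 cases, lost a call in 65 and gained one in 21. Single-site widths kept both in 199 cases, lost a call in 29, gained one in 42 and reversed in 4. The genome-wide baseline, the peak of each array and the minimum of 2 probes per bin changed the direction or call of no mean width, mean height or total count they apply to. Noise between neighbouring bins limits the widths, which in simulated peaks read 28.9% to 78.7% of their true length at the noise of chk2 replicate 1. Signal over background alone does not give this noise: mus101 replicate 1 had a noise of 0.63 with 97.4% of red probes above background, and DNL4 replicate 2 had 0.27 with 83.9%.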

Other observations

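The stretches and the probes compared here were chosen after the data were seen.

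A stretch on 2L, 12864001 to 12901000, was raised in every group, at 0.90 ± 0.10 over 24 arrays (SD). The search for amplified regions also found stretches on X at 9837001 to 9863000 (0.75) and 18541001 to 18593000 (0.77), against a median of 0.37 for all of X, and at 2-fold it found neither. chk1 and ligIV shared a gain on 2R, 16157001 to 16165000, at 0.96 and 0.97, and chk2 had a gain on 2R, 2649001 to 2656000, at 0.93. At the latter stretch spnA replicate 3, the highest array outside chk2, measured 0.66, and the median outside chk2 was 0.14. At 135 probes on X that were lowered in the ligIV arrays, DNL4 replicate 1 measured -4.11, and the library labelled DNL4 replicate 2 measured 0.07. chk2 replicate 3 was lowest at probes lowered in chk2_CyO (-1.67), and measured -0.33 at those lowered in the chk2 arrays. The chk2_CyO arrays themselves measured -1.98 and -2.25 at probes lowered in the other array of their group. Whether this bears on the label of chk2 replicate 3, and so on the chk2 contrasts, was not tested. At probes lowered in the brca2 arrays, brca2 replicate 3 measured -3.39 on X and -3.65 on chromosome 3, and -0.67 on chromosome 2.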
